A study of Sus scrofa with 10 samples.

How the data were processed

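The series holds 4 tables, each with pLCDM and 1 other group, in which per the labels each column is 1 library. Per the submitters' processing notes the reads were aligned with HISAT2 2.2.1; the counter, genome build and annotation are not given in the sources used here. The deposited counts are raw read counts per gene made by the authors, and no molecular identifiers were used. The deposited FPKM are the authors' values per gene length and read total, and the gene length and reads behind them are not given in the sources used here. Some genes with 0 counts have an FPKM above 1, and an FPKM of 0 stands beside over 200 counts for 13 and 8 genes of the 2 TE libraries and 19 and 20 of the ICM libraries. The FPKM were therefore not made from the deposited counts alone. The authors' deposited tables also hold a log2 fold change of each group against pLCDM, made before deposit by a test that is not given in the sources used here. The authors' deposited p-value and adjusted p come from that same test. Genes are named by the symbols of the deposited tables, which give no positions.

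Rows of one symbol with the same counts were taken as 1 gene, and symbols with several different rows were left out (152 in the ICM table, 154 in the TE table, 2 in each of the others). This left 8987 genes for ICM, 9063 for TE, 10174 for pLCDM-TSC and 9508 for pPSC(KOFL). Counts of pLCDM were the same in all 4 tables, so the tables were joined over their 8795 shared genes for TE minus ICM and for the interaction. The columns of pPSC(KOFL) carry the numbers 2 and 3 while the titles carry other numbers, so these columns were matched to the group alone. Columns matched in this way are used only up to the number of samples of the group. The 2 pPSC(KOFL) count columns were therefore used, and 2 columns, the pPSC(KOFL) FPKM, were not.

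The rest of the processing was done here with R 4.3.3. Genes with enough counts (filterByExpr) were scaled by TMM and tested with edgeR 4.0.16 by a robust quasi-likelihood F test, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The SE of a log2 fold change is its size divided by the root of F. Where 1 group had no read of a called gene, the fold is given as at least the ratio to a floor of 3 counts per library. Interactions, alternatives and genes that did not pass are given as fitted log2 values, which are not exact where a group had no read. Gene lists were fixed in number (33) and membership before the data were examined, and those with at least 5 tested members were tested with camera from limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison. Genes in a list were also adjusted over the list alone. Named genes were 22 landmark genes, up to 4 members per list with the smallest p, members moving against their list, and the 5 largest rises and falls by fitted log2 fold change, which takes genes without a read at a small value, among called genes with at least 10 CPM in the higher group. Of the landmarks, POU5F1, NANOG, SOX2, KLF4, SALL4, KRT7, HAND1, TBXT and COL1A1 have no row used in these tables and were not analysed here. GATA3 has none in that of pLCDM-TSC, and so is missing from the joined genes too.

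Alternatives to the scaling, filter, test, fit, unit and libraries were also listed before the data were examined, with DESeq2 1.42.0 and limma-voom among the tests; 1 was added afterwards, leaving out genes without a read in a compared group. The code was tested on simulated data with known folds. At a fold of 4, it recovered 67.2% of the genes for pLCDM-TSC, 94% for pPSC(KOFL), 46.3% for TE, 0% for ICM and 1.49% for TE minus ICM; for the interaction it recovered 0% at each fold tried. Genes without a change made up 5.93% of the calls for pLCDM-TSC, 15.1% for pPSC(KOFL), 11.7% for TE and 4.76% for TE minus ICM, and the single call for ICM was false. Replicates are not stated to be separate cultures or animals, so the p-values measure only the spread between these samples. The authors' deposited table calls 3144 of the tested genes for pLCDM-TSC, 4800 for pPSC(KOFL), 2558 for ICM and 4199 for TE, and the log2 fold changes of the authors' deposited table had r of 0.996, 0.992, 0.999 and 0.999 with those given here, across genes that are not independent replicates.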

Results

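RNA from pig pluripotent stem cells and blastocyst tissues was measured by Smart-seq2, a sequencing method for full-length complementary DNA from small samples, in 5 groups of 2 libraries each. The pLCDM group holds pluripotent stem cells established from blastocysts in LCDM medium, which contains human LIF, the GSK3 inhibitor CHIR99021, dimethindene maleate and minocycline. The pPSC(KOFL) group holds pluripotent stem cells established from blastocysts in KOFL, a chemically defined medium without serum or feeder cells. The pLCDM-TSC group holds pLCDM cells cultured in human trophoblast stem cell conditions. The inner cell mass (ICM), which forms the embryo proper, and the trophectoderm (TE), which forms the trophoblast of the placenta, came from in vivo embryos of another series. The total count per library was 14426253 to 15350514 for pLCDM 1 and 12348366 to 13065683 for pLCDM 2, depending on the table. It was 16343032 and 18638430 for pLCDM-TSC 1 and 2, 6788706 and 7170741 for pPSC(KOFL) 2 and 3, 12329116 and 7222353 for ICM 1 and 2, and 11708893 and 12823132 for TE 2 and 3. Between 8187 and 8812 genes had a read in each cultured library and between 6109 and 6809 in each embryo library. Of the 8795 genes that all 4 tables hold, 8006 had enough counts. Across these, Spearman's rho between the libraries of a group was 0.838 for ICM, 0.942 for TE, 0.964 for pLCDM-TSC, 0.969 for pLCDM and 0.987 for pPSC(KOFL). Genes are not independent replicates. The mean rho between groups was 0.818 for pLCDM and pLCDM-TSC, 0.754 for pLCDM and pPSC(KOFL), 0.835 for ICM and TE, 0.597 for pLCDM and ICM and 0.605 for pLCDM and TE. All fold changes below are log2 values ± SE from edgeR with 2 libraries per group, and all levels are means in CPM, counts scaled to library size.

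**Figure D1:**
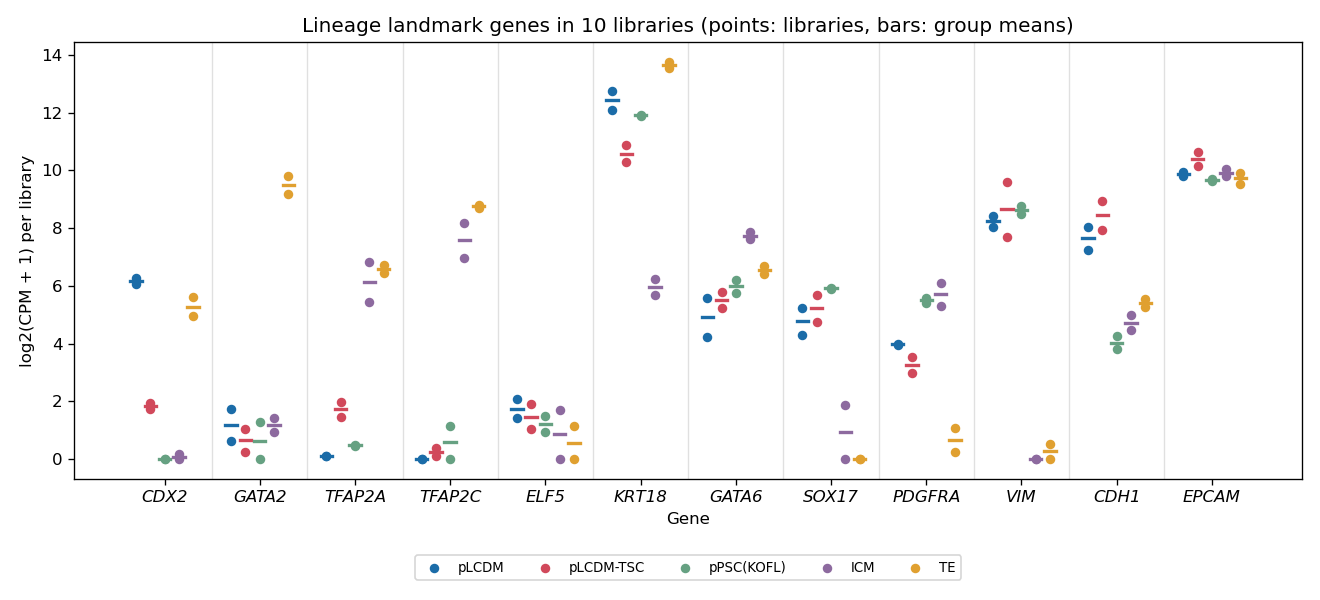
Level of 12 landmark genes of early lineages, as log2(CPM + 1) on the vertical axis, in the 5 groups; points are libraries and bars are means of 2 libraries. CDX2 had a mean of 70.8 CPM in pLCDM, 38.8 CPM in TE and 2.57 CPM in pLCDM-TSC.

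Cells moved from LCDM into trophoblast stem cell medium were compared with their parent cells to ask what changed with the medium. CDX2, a transcription factor that sets up the trophectoderm, fell from 73.3 ± 8.59 to 2.58 ± 0.384 CPM (SD), a change of -4.82 ± 0.41 (adjusted p = 0.00114 by edgeR). GDF3, a TGF-beta family ligand of pluripotent cells, fell by 8.51 ± 0.62, and GATA4, a hypoblast transcription factor, fell by 3.74 ± 0.36. ITGA6, an integrin subunit used to mark trophoblast stem cells, rose by 4.67 ± 0.31, LGALS3, a galectin of trophoblast, by 3.78 ± 0.36, and TAGLN, an actin-binding protein of smooth muscle and fibroblasts, by 13.13 ± 0.85. TAGLN was nearly unread in pLCDM, and pLCDM minus pPSC(KOFL) gave -11.79 for it. Its low count in pLCDM is not taken as absence of the transcript. Of 7782 genes tested, 1087 rose and 1450 fell, 141 of them with no read in one of the groups.

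Among 13 trophoblast regulators, 2 rose and 3 fell, both over all genes and adjusted over the list alone. TFAP2A rose by 5.02 ± 1.15 to no more than 2.36 CPM, and PPARG, a nuclear receptor of trophoblast, by 2.65 ± 0.60. TEAD4, the partner of YAP in the first lineage choice, fell by 2.52 ± 0.44, beside CDX2. GATA2 (-1.22 ± 1.24) and ELF5 (-0.42 ± 0.87) did not pass, which does not show that they stayed unchanged. GATA2 was little read in pLCDM, at a level given below beside that of TE. GATA3 has no row used for this comparison, and no value is given for TFAP2C. Camera did not call the list (adjusted p = 0.937). Of 6 trophoblast differentiation genes, 3 rose and 1 fell, again the same counts adjusted over the list alone (camera adjusted p = 0.279). SPP1, a secreted adhesion protein of the conceptus and uterus, rose by 4.68 ± 1.01 and DAB2, an endocytic adaptor, by 2.36 ± 0.68, while FURIN, a proprotein convertase, fell by 4.44 ± 0.99. TFAP2A did not pass without any 1 of the 4 libraries (4.60 to 5.35), PPARG without pLCDM 2 (2.33), SPP1 without either pLCDM-TSC library (5.24 and 3.84) and DAB2 without pLCDM-TSC 2 or pLCDM 2 (1.05 and 1.97).

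Pluripotency genes went both ways. Of 8 naive pluripotency genes, 3 rose and 2 fell, or 4 and 3 adjusted over the list alone (camera adjusted p = 0.522). TFCP2L1, a naive state transcription factor, rose by 6.78 ± 0.97, IL6ST, the shared receptor subunit for LIF, by 1.89 ± 0.38, and TBX3 fell by 2.88 ± 0.34. Of 12 primed pluripotency genes, 0 rose and 5 fell, or 1 and 5 adjusted over the list alone (camera adjusted p = 0.23), among them ETV4 (-2.97 ± 0.59), an ERK-responsive factor, and the DNA methyltransferases DNMT3A (-1.10 ± 0.27) and DNMT3B (-1.63 ± 0.41). ETV4 missed the threshold without pLCDM 2 (-2.36), DNMT3A without pLCDM 1 or 2 (-1.11 and -1.07) and DNMT3B likewise (-1.52 and -1.72). Of 24 hypoblast and extraembryonic endoderm genes, 3 rose and 6 fell, or 4 and 6 adjusted over the list alone, while GATA6 (0.43 ± 0.53) and SOX17 (0.42 ± 0.51) did not pass (camera adjusted p = 0.83). Beside GATA4, COL4A2, a basement membrane collagen, fell by 2.37 ± 0.30, whereas AFP, the fetal serum protein made in yolk sac, was at least 58.8-fold higher in pLCDM-TSC, since pLCDM held no read of it.

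Of 17 integrin and laminin genes, 8 rose and 3 fell, or 10 and 3 adjusted over the list alone, with a median of 2.28 (camera adjusted p = 0.109, the smallest of the 29 lists tested). ITGB6, a subunit of an epithelial receptor that activates TGF-beta, rose by 8.70 ± 1.18, and ITGB4, the hemidesmosome subunit, fell by 3.74 ± 0.66. Of 17 genes of epithelial junctions and keratins, 1 rose and 7 fell, the same counts adjusted over the list alone (camera adjusted p = 0.194). SPINT1, a membrane protease inhibitor, fell by 3.33 ± 0.36, as did JUP (-4.03 ± 0.49), the plakoglobin of desmosomes, and KRT18 (-1.90 ± 0.38), a simple epithelial keratin, while F11R, a tight junction adhesion molecule, rose by 1.08 ± 0.27. Of 16 fibroblast and mesenchyme genes, 6 rose and 3 fell, or 8 and 3 adjusted over the list alone (camera adjusted p = 0.141), among them COL1A2, a fibrillar collagen chain, at 5.62 ± 0.57 and FBLN2, a fibulin, at -2.92 ± 0.44. Of 15 YAP and TEAD targets, 5 rose and 1 fell, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.182), led by PTPN14 (5.21 ± 0.33) and ANKRD1 (3.49 ± 0.42). KRT18 did not pass without pLCDM 1 (-1.53), nor F11R without pLCDM 1 or 2 (1.17 and 1.00). VIM (0.65 ± 0.58), CDH1 (0.79 ± 0.43) and EPCAM (0.51 ± 0.29) did not pass, and each passed without pLCDM-TSC 2, at 1.31, 1.21 and 0.74.

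Of 16 glycolysis genes, 2 rose and 7 fell, or 2 and 8 adjusted over the list alone, with a median of -1.19 (camera adjusted p = 0.141). GAPDH, a glycolytic enzyme often used as a reference gene, fell by 13.42 ± 0.61 from 14440 to 1.31 CPM, ALDOC, a fructose-bisphosphate aldolase, was at least 1720-fold lower, and TPI1, triosephosphate isomerase, rose by 10.56 ± 1.17. GAPDH and TPI1 kept their calls on FPKM, but TPI1 had 0 counts beside an FPKM of at least 589 in every embryo library. Levels near 0 CPM of GAPDH in pLCDM-TSC and of TPI1 in pLCDM are therefore not taken as absence of the transcript. Of 20 cholesterol synthesis genes, 2 rose and 8 fell, or 3 and 9 adjusted over the list alone (camera adjusted p = 0.194). DHCR24, which makes the last reduction of the pathway, fell by 4.81 ± 0.40, as did SREBF2 (-3.55 ± 0.30), its main transcription factor, while PCSK9, which lowers LDL receptor levels, rose by 5.05 ± 0.82. Of 13 BMP target genes, 0 rose and 5 fell, or 0 and 6 adjusted over the list alone (camera adjusted p = 0.182), including MSX1 (-2.71 ± 0.52). Among genes with no read in one group, ENOSF1 was at least 2000-fold higher and TNFRSF12A at least 4230-fold lower in pLCDM-TSC. Each was read in all 4 other groups, ENOSF1 being missing from pLCDM alone and TNFRSF12A from pLCDM-TSC alone. These counts of 0 are not taken as absence of the transcripts. The genes given as risen or fallen in these 5 paragraphs had adjusted p values from 0.000287 for GAPDH to 0.0392 for DAB2. By camera, 0 of 29 lists were called, with 6 at an unadjusted p under 0.05, against 4 by fry, and the smallest adjusted p = 0.776 with an estimated correlation. Without pLCDM 1, 524 genes rose and 881 fell, and without pLCDM 2, 521 and 802; 4 lists were called without pLCDM-TSC 2 and 2 without pLCDM 2. Fitted together with the other 3 groups, these genes did not pass: GATA4 (-3.69), TEAD4 (-2.46), PPARG (2.71), DAB2 (2.41), ETV4 (-2.91), DNMT3A (-1.04), DNMT3B (-1.58), COL4A2 (-2.31), ITGB4 (-3.68), F11R (1.13) and MSX1 (-2.64). On the deposited FPKM, COL4A2 (1.04), DNMT3A (1.66), DNMT3B (0.15) and FBLN2 (0.28) took the other sign. Between the longest and the shortest quartile of genes by span, the median log2 fold change differed by -0.87 (bootstrap interval -0.98 to -0.74) for pLCDM minus pLCDM-TSC. The difference was 0.89 (0.75 to 1.04) for pLCDM-TSC minus pPSC(KOFL), so the fold changes of pLCDM-TSC carry a trend with gene length.

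The 2 media for pluripotent cells were then compared, as pLCDM minus pPSC(KOFL). CDX2 was at least 119-fold higher in pLCDM (63.6 ± 6.1 CPM, SD) than in pPSC(KOFL), where it had no read (adjusted p = 5.99e-05 by edgeR). CDH1, the epithelial cadherin, was higher by 3.67 ± 0.34, at 185 against 14.6 CPM, and GATA3, a trophoblast transcription factor, by 1.40 ± 0.33. PDGFRA, a receptor of hypoblast and mesoderm, was lower by 1.66 ± 0.26, as were SOX17 (-1.16 ± 0.35), an endoderm transcription factor, and GDF3 (-2.28 ± 0.23). Of 7557 genes tested, 2745 were higher and 2189 lower in pLCDM, 325 of them with no read in one of the groups.

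Of 15 glycolysis genes, 14 were higher and 0 lower in pLCDM, the same counts adjusted over the list alone, with a median of 4.05 (camera adjusted p = 0.000173; adjusted p = 0.832 with an estimated correlation). PDK1, a kinase that holds pyruvate back from mitochondria, was higher by 7.49 ± 0.32, HK2, a hexokinase, by 5.32 ± 0.23 and PGK1 by 3.57 ± 0.18. Of 13 cytosolic ribosomal protein genes, 1 was higher and 12 lower, the same counts adjusted over the list alone, with a median of -1.32 (camera adjusted p = 0.0028; adjusted p = 0.832 with an estimated correlation). RPL10A stood at 0.602 against 3046 CPM, a change of -12.29 ± 0.31, and RPS23 (-2.46 ± 0.19) and RPS3A (-2.25 ± 0.19) were lower too. The low count of RPL10A in pLCDM is not taken as absence of the transcript either. By camera, 2 of 29 lists were called, against 19 by fry. Of 12 nuclear genes of oxidative phosphorylation, 1 was higher and 8 lower, or 1 and 9 adjusted over the list alone (camera adjusted p = 0.0634), with NDUFB10 (3.12 ± 0.31) and NDUFS1 (-1.91 ± 0.19), both of complex I, on opposite sides.

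Of 9 WNT target genes, 6 were higher and 2 lower in pLCDM (camera adjusted p = 0.484), and of 13 BMP target genes, 9 were higher and 1 lower, or 10 and 1 adjusted over the list alone (camera adjusted p = 0.127). The WNT counts were the same adjusted over the list alone. AXIN2, a feedback inhibitor of WNT signalling, was at least 71.8-fold higher, LEF1, a WNT effector, higher by 5.68 ± 0.59, and AMBP, a plasma protein precursor, was lower by 5.86 ± 0.69. MSX1 was higher by 5.44 ± 0.44, ID4, an inhibitor of basic helix-loop-helix factors, by 6.14 ± 0.58, and BMPER, a BMP-binding protein, was lower by 1.70 ± 0.25. Of 22 hypoblast and extraembryonic endoderm genes, 12 were higher and 5 lower, also adjusted over the list alone (camera adjusted p = 0.548). APOA1, an apolipoprotein of visceral endoderm, was higher by 8.92 ± 0.46, SPARC, a matrix protein of parietal endoderm, by 4.65 ± 0.19, and RBP4, the plasma carrier of retinol, at least 124-fold. GATA6 (-1.02 ± 0.45) did not pass, though it did without pLCDM 2 (-1.88), and SOX17 did not pass without either pPSC(KOFL) library (-1.15 and -1.18).

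Of 6 naive pluripotency genes, 4 were higher and 0 lower in pLCDM, also adjusted over the list alone (camera adjusted p = 0.315), led by NR5A2, a nuclear receptor that can drive POU5F1, at 4.71 ± 0.72 and TBX3 at 2.67 ± 0.42. Of 12 primed pluripotency genes, 4 were higher and 1 lower, or 3 and 0 adjusted over the list alone (camera adjusted p = 0.484), with the WNT receptor FZD7 at 7.28 ± 0.33 and SALL2, a zinc finger factor, at 4.18 ± 0.28. Of 12 trophoblast regulators, 6 were higher and 2 lower, also adjusted over the list alone (camera adjusted p = 0.491), with TEAD4 at 1.90 ± 0.40 and SATB2, a chromatin organiser, at -1.47 ± 0.33. Of 17 genes of epithelial junctions and keratins, 9 were higher and 2 lower, also adjusted over the list alone (camera adjusted p = 0.315), with the desmosome genes DSP at 2.81 ± 0.19 and PKP2 at 2.91 ± 0.18, and F11R at -2.47 ± 0.18. KRT18 (0.50 ± 0.24), VIM (-0.47 ± 0.20), EPCAM (0.13 ± 0.16), GATA2 (0.96 ± 1.33) and ELF5 (0.79 ± 0.75) did not pass, but KRT18 (0.80) and VIM (-0.68) did without pLCDM 2. Of 20 cholesterol synthesis genes, 8 were higher and 9 lower, also adjusted over the list alone (camera adjusted p = 0.939). The list's median was -0.22 and its mean 0.29, with LDLR, the LDL receptor, at 7.16 ± 0.31 and FDPS, a farnesyl diphosphate synthase, at -9.55 ± 0.64. Among genes with no read in one group, FTL, ferritin light chain, was at least 2340-fold higher and ENOSF1 at least 9420-fold lower. FTL also had 0 counts beside a high FPKM in every embryo library, and the FPKM of pPSC(KOFL) were not used, so its count of 0 is not taken as absence. The count of 0 of ENOSF1 in pLCDM is the one already met against pLCDM-TSC, and is not taken as absence either. The genes given as higher or lower in these 4 paragraphs had adjusted p values from 1.16e-05 for RPL10A to 0.0239 for SOX17. Fitted together with the other 3 groups, BMPER (-1.67), PDGFRA (-1.63), RPS23 (-2.43), SOX17 (-1.14) and TEAD4 (1.92) did not pass. Nor did SATB2 (-0.85) and SOX17 (-0.54) with library size alone, where KRT18 (1.12) and EPCAM (0.76) passed. VIM passed with RLE scaling and with DESeq2 (-0.63 in both), and GATA6 with DESeq2 (-1.18). In an earlier run on FPKM, which are not used here, SOX17, EPCAM and PKP2 lay on the other side. The share of called genes that were higher in pLCDM was 55.6% with TMM scaling and 73.2% with library size alone, which moved the median of all genes from 0.26 to 0.89.

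**Figure D2:**
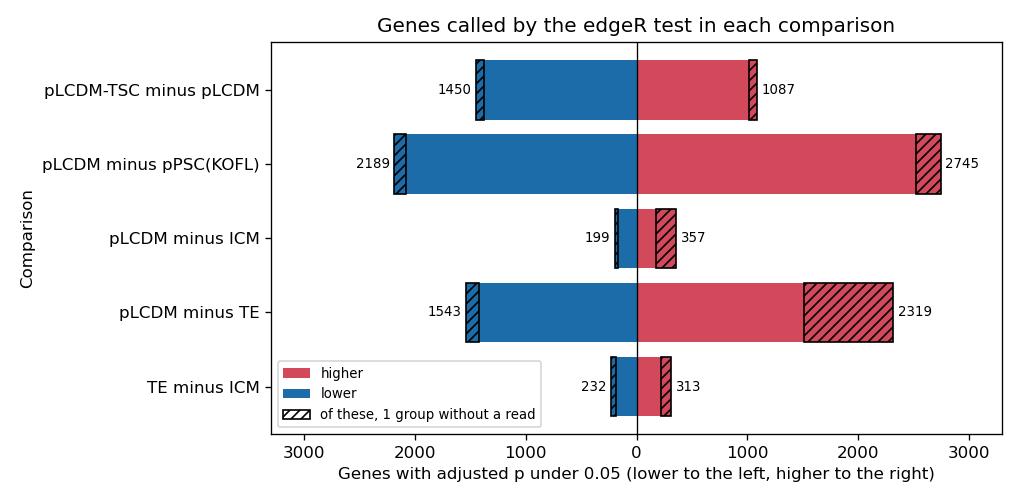
Number of genes higher (to the right) and lower (to the left) at an adjusted p under 0.05 by edgeR in each of 5 comparisons. The hatched part of each bar counts genes with no read in 1 of the compared groups. Called genes numbered 4934 for pLCDM minus pPSC(KOFL) and 556 for pLCDM minus ICM.

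pLCDM cells were set against the ICM, the pluripotent tissue of the blastocyst. KRT18 was higher by 6.53 ± 0.52 in pLCDM, at 6763 against 73.4 CPM (adjusted p = 0.0279 by edgeR), and KRT8, its keratin partner, by 6.06 ± 0.60. VIM, an intermediate filament of mesenchyme and cultured cells, was at least 1100-fold higher, and CDX2 was higher by 10.30 ± 1.50, at 84.5 against 0.0691 CPM. TFAP2C, which acts in trophoblast and naive pluripotent cells, was at least 1090-fold lower, having no read in pLCDM and a mean of 247 CPM in the ICM, and TFAP2A was lower by 10.08 ± 1.24. Of 7379 genes tested, 357 were higher and 199 lower in pLCDM, and 216 of them had no read in one of the groups. Between the 2 ICM libraries rho was 0.838, and the biological coefficient of variation was 79.3%, against 27.8% in the comparison with pPSC(KOFL).

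Of 8 naive pluripotency genes, 0 were higher and 4 lower in pLCDM, also adjusted over the list alone, with a median of -5.41 (camera adjusted p = 0.00038; adjusted p = 0.648 with an estimated correlation). STAT3, the effector of LIF, was lower by 4.77 ± 0.54, as were PECAM1 (-7.79 ± 0.89), a surface marker of naive cells, TFCP2L1 (-9.66 ± 1.39) and KLF17 (-6.19 ± 0.93). Of 8 WNT target genes, 4 were higher and 0 lower, or 6 and 0 adjusted over the list alone, with a median of 6.12 (camera adjusted p = 0.0125; adjusted p = 0.648 with an estimated correlation). LEF1 was higher by 11.71 ± 1.21, BMP4, a BMP ligand, by 5.58 ± 0.58, and DKK1, a secreted WNT inhibitor, at least 619-fold. Of 16 glycolysis genes, 5 were higher and 0 lower, or 10 and 0 adjusted over the list alone, with a median of 4.23 (camera adjusted p = 0.0074; adjusted p = 0.648 with an estimated correlation). GAPDH was higher by 7.21 ± 1.00 and PGK1 by 4.19 ± 0.60. Of 17 cholesterol synthesis genes, 6 were higher and 0 lower, or 9 and 1 adjusted over the list alone, with a median of 4.08 (camera adjusted p = 0.0243; adjusted p = 0.648 with an estimated correlation). SQLE, squalene epoxidase, was higher by 6.32 ± 0.56 and INSIG1, which retains the sterol sensor in the endoplasmic reticulum, by 9.12 ± 0.97. Of 14 YAP and TEAD targets, 1 was higher and 0 lower, or 8 and 0 adjusted over the list alone, and the median was 5.44, or 4.46 with genes without a read at their bound (camera adjusted p = 0.0298; adjusted p = 0.648 with an estimated correlation). That gene was DLC1, a Rho GTPase-activating protein, at 9.25 ± 0.99. Of 12 nuclear genes of oxidative phosphorylation, 0 were higher and 1 lower, also adjusted over the list alone, with a median of -0.99 (camera adjusted p = 0.0432; adjusted p = 0.654 with an estimated correlation), the gene being NDUFV1 of complex I at -5.20 ± 0.46. TFCP2L1 did not pass without either pLCDM library (-9.55 and -9.71), nor KLF17 without pLCDM 1 (-5.68).

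Of the lists that camera did not call, the 15 trophoblast regulators had 2 members higher and 2 lower, or 4 and 3 adjusted over the list alone, with a median of 0.18, a mean of -0.63 and a test in the lower direction (camera adjusted p = 0.483). GATA3 (4.33 ± 0.97), GATA2 (0.17 ± 1.19) and ELF5 (1.09 ± 2.10) did not pass. Of 18 hypoblast and extraembryonic endoderm genes, 5 were higher and 0 lower, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.138), among them FN1, fibronectin, at 3.81 ± 0.53 and FOXA2, an endoderm factor, at least 225-fold. GATA6 (-2.69 ± 0.66), SOX17 (4.43 ± 2.10) and PDGFRA (-1.82 ± 0.74) did not pass. Of 17 genes of epithelial junctions and keratins, 4 were higher and 0 lower, or 8 and 1 adjusted over the list alone (camera adjusted p = 0.345), with PKP2 at 11.11 ± 1.85 and CDH1 at 3.04 ± 0.56, while EPCAM (-0.05 ± 0.37) did not pass. On FPKM, CDH1 was lower in pLCDM (-2.71) and so was EPCAM (-3.36). The median of all genes tested on FPKM was itself -2.27. The gene lengths implied by counts and FPKM differ between pLCDM and ICM, so FPKM are not comparable between them. GDF3 was higher by 3.98 ± 0.67. Among genes with no read in one group, SELENOP, a secreted selenium carrier, was at least 9860-fold higher and MRPL43, a mitochondrial ribosomal protein, at least 4180-fold lower. MRPL43 had no read in pLCDM, and the comparisons with pPSC(KOFL) and TE gave bounds of 5380-fold and 4680-fold as well. Its count of 0 in pLCDM is not taken as absence of the transcript. The genes given as higher or lower in these 3 paragraphs had adjusted p values from 0.0279 for KRT18 to 0.0476 for CDH1. CDH1 did not pass without pLCDM 1 or 2 (3.39 and 2.61), nor GDF3 without pLCDM 2 (3.68), while GATA3 (5.52 and 3.62), GATA6 (-2.61 and -2.81), SOX17 (11.54 and 3.38) and PDGFRA (-1.44 and -2.19) passed without ICM 1 and without ICM 2, and ELF5 (8.23) without ICM 2. With DESeq2, GATA3 (4.29), GATA6 (-2.73), SOX17 (4.43) and PDGFRA (-1.87) passed. So did GATA3 and GATA6 with limma-voom (4.59 and -2.89) and with the replicate number as a block (4.57 and -2.85), and GATA6 (-2.78) and SOX17 (4.31) in the fit of all 5 groups.

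By camera, 6 of 29 lists were called, against 17 by fry, 3 without ICM 1 and 1 without pLCDM 2. Without ICM 1, 3247 genes were higher and 1914 lower, without ICM 2, 2743 and 1737, and without pLCDM 2, 288 and 121; without pLCDM 1, 126 genes were lower. The naive pluripotency call was kept in each case, but the WNT call was lost without ICM 1 (adjusted p = 0.18), ICM 2 (adjusted p = 0.0741) or pLCDM 2 (adjusted p = 0.0538), with a highest value over its alternatives of 0.648. The YAP and TEAD call was lost without ICM 1 (adjusted p = 0.207), pLCDM 1 (adjusted p = 0.0781) or pLCDM 2 (adjusted p = 0.0632). The glycolysis call was lost without pLCDM 2 (adjusted p = 0.0538), the cholesterol call without pLCDM 1 (adjusted p = 0.0975) or pLCDM 2 (adjusted p = 0.0538), and the oxidative phosphorylation call without ICM 1 (adjusted p = 0.478) or pLCDM 2 (adjusted p = 0.111). The ICM and TE libraries came from another series, so cell source and study cannot be told apart in the comparisons of pLCDM with either tissue.

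pLCDM cells were also set against the TE. CDX2 stood at 72.8 ± 7.9 CPM in pLCDM and 40.8 ± 12.3 CPM (SD) in TE, a difference of 0.84 ± 0.40 that did not pass (adjusted p = 0.128 by edgeR). Other trophoblast factors were lower in pLCDM, with GATA2, a regulator of trophoblast genes, at 1.45 against 775 CPM (-9.07 ± 0.79), GATA3 at -2.72 ± 0.45, TFAP2A at -10.39 ± 0.62, and TFAP2C at least 2320-fold lower. As given above, TFAP2A and TFAP2C were also lower in pLCDM than in the ICM, so their low levels are not particular to the comparison with TE. Of the hypoblast markers, SOX17 was at least 101-fold higher in pLCDM, and PDGFRA was higher by 4.42 ± 1.11. Of 7443 genes tested, 2319 were higher and 1543 lower in pLCDM, and 927 of them had no read in one of the groups.

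Of 15 trophoblast regulators, 2 were higher and 9 lower in pLCDM, also adjusted over the list alone, with a median of -2.72 (camera adjusted p = 0.0127; adjusted p = 0.614 with an estimated correlation). Against the list's direction, ID2, an inhibitor of basic helix-loop-helix factors, was higher by 7.58 ± 0.44. Of 7 trophoblast differentiation genes, 1 was higher and 6 lower, also adjusted over the list alone, with a median of -4.84 (camera adjusted p = 0.0127; adjusted p = 0.614 with an estimated correlation). PTGS2 (-13.99 ± 1.09) and PTGES (-4.84 ± 0.33), enzymes of prostaglandin E synthesis, and DAB2 (-6.38 ± 0.53) were lower, and SPP1 was at least 129-fold higher. The differentiation call was lost without pLCDM 1 (adjusted p = 0.0542) or pLCDM 2 (adjusted p = 0.0583), with a highest value over its alternatives of 0.614.

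Of 20 hypoblast and extraembryonic endoderm genes, 16 were higher and 0 lower in pLCDM, or 17 and 1 adjusted over the list alone (camera adjusted p = 0.00272; adjusted p = 0.614 with an estimated correlation). The median was 6.97, or 6.17 with genes without a read at their bound. APOA1 was at least 17800-fold and SPARC at least 2110-fold higher, HNF4A, a nuclear receptor of visceral endoderm, was higher by 8.25 ± 0.54, while GATA6 (-1.55 ± 0.53) did not pass. Of 12 primed pluripotency genes, 9 were higher and 0 lower, also adjusted over the list alone (camera adjusted p = 0.0173; adjusted p = 0.614 with an estimated correlation), with a median of 6.50, or 4.98 with genes without a read at their bound. SALL2 was at least 499-fold higher and ZIC2, a zinc finger factor of the primed state, was higher by 4.72 ± 0.56. Of 15 glycolysis genes, 13 were higher and 1 lower, also adjusted over the list alone, with a median of 4.42 (camera adjusted p = 0.00743; adjusted p = 0.614 with an estimated correlation), including GAPDH (5.48 ± 0.32) and PDK1 (5.82 ± 0.41). Of 12 nuclear genes of oxidative phosphorylation, 2 were higher and 7 lower, or 2 and 8 adjusted over the list alone, with a median of -1.69 (camera adjusted p = 0.0295; adjusted p = 0.614 with an estimated correlation), led by NDUFV1 at -6.41 ± 0.35. The primed call was lost without TE 2 (adjusted p = 0.0567) and the oxidative phosphorylation call without TE 2 (adjusted p = 0.0567) or TE 3 (adjusted p = 0.0527), while the hypoblast, regulator and glycolysis calls were kept without each library. By camera, 6 of 28 lists were called, against 22 by fry.

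Of 9 naive pluripotency genes, 1 was higher and 6 lower in pLCDM, also adjusted over the list alone (camera adjusted p = 0.0505), with TFCP2L1 at -9.28 ± 0.79 and TBX3 at -2.04 ± 0.29. Of 18 cholesterol synthesis genes, 13 were higher and 2 lower, or 13 and 3 adjusted over the list alone (camera adjusted p = 0.0505), with HMGCR, the rate-limiting enzyme of the pathway, at 4.14 ± 0.29. Of 14 fibroblast and mesenchyme genes, 9 were higher and 2 lower, also adjusted over the list alone (camera adjusted p = 0.0914), with FBLN2 at 8.38 ± 0.43 and VIM at 10.33 ± 0.87; within pLCDM, COL3A1, a fibroblast collagen, was higher in library 2 than in library 1 by 4.41. Of 17 genes of epithelial junctions and keratins, 4 were higher and 5 lower, also adjusted over the list alone (camera adjusted p = 0.203). CLDN4, a tight junction claudin, was lower by 4.90 ± 0.31, as were JUP (-4.66 ± 0.30) and KRT18 (-1.22 ± 0.30), CDH1 was higher by 2.27 ± 0.39, and EPCAM (0.10 ± 0.27) and ELF5 (1.99 ± 1.75) did not pass. On FPKM, CDH1 (-2.87) and EPCAM (-3.13) were lower in pLCDM. The median of all genes tested on FPKM was itself -2.17, and FPKM are not comparable between pLCDM and TE for the same reason as with ICM. GDF3 was higher by 2.50 ± 0.36. CLDN8, another claudin, had no read in pLCDM and was at least 12500-fold lower. The genes given as higher or lower in these 4 paragraphs had adjusted p values from 0.000328 for TFAP2C to 0.019 for PDGFRA. CDX2 (1.21) and ELF5 (8.15) passed without TE 2 and GATA6 (-2.40) without pLCDM 2. GATA6 also passed with DESeq2 (-1.54), without a low count filter and in the fit of all 5 groups (-1.53 in both). PDGFRA did not pass without pLCDM 1 or 2 (4.43 and 4.45), and SPP1 did not without TE 2, TE 3 or pLCDM 2 (11.99, 11.97 and 9.74). These values of SPP1, which had no read in TE, are fitted ones and not exact. Without pLCDM 2, 1166 genes were higher and 882 lower, and without pLCDM 1, 1242 and 942. Of the called genes, 60% were higher in pLCDM with TMM scaling and 69.2% with library size alone, which moved the median of all genes from 0.38 to 0.78. KRT18 (-0.83) then did not pass and CDX2 (1.23) did.

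TE was compared with ICM within the embryo libraries, as the tissue difference that the cultured pair was to be held against. KRT18 was higher in TE by 7.63 ± 0.45, at 12750 against 64.4 CPM (adjusted p = 0.000378 by edgeR), and KRT8 by 6.99 ± 0.68. CDX2 was higher by 9.36 ± 1.20, at 38.4 against 0.0607 CPM, and GATA2 by 9.10 ± 1.31. STAT3 was lower by 4.77 ± 0.52, NR5A2 at least 129-fold, and the hypoblast genes FN1 (-9.35 ± 0.76), HNF4A (-9.39 ± 0.91) and PDGFRA (-6.37 ± 0.96) were lower too. Of 8006 genes tested in a fit of all 5 groups, 313 were higher and 232 lower in TE.

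Of 17 genes of epithelial junctions and keratins, 6 were higher and 0 lower in TE, or 7 and 0 adjusted over the list alone, with a median of 1.51 (camera adjusted p = 1.2e-05; adjusted p = 0.163 with an estimated correlation), including OCLN, occludin of tight junctions, at 6.19 ± 0.87 and PKP2 at 8.93 ± 1.16. CDH1 (0.65 ± 0.47) and EPCAM (-0.27 ± 0.33) did not pass. Of 6 trophoblast differentiation genes, 3 were higher and 0 lower, or 5 and 0 adjusted over the list alone, with a median of 4.80 (camera adjusted p = 0.000434; adjusted p = 0.181 with an estimated correlation), with LGALS3 at 7.55 ± 0.57 and DAB2 at 6.96 ± 0.81. Of 14 trophoblast regulators, 3 were higher and 0 lower, also adjusted over the list alone, with a median of 0.95 (camera adjusted p = 0.0109; adjusted p = 0.246 with an estimated correlation), while TFAP2A (0.20 ± 0.62), TFAP2C (0.98 ± 0.82) and ELF5 (-0.99 ± 2.07) did not pass. Of 9 naive pluripotency genes, 0 were higher and 3 lower, or 0 and 4 adjusted over the list alone (camera adjusted p = 0.0405; adjusted p = 0.387 with an estimated correlation). Of 21 hypoblast and extraembryonic endoderm genes, 0 were higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.0405, and adjusted p = 0.242 with an estimated correlation). GATA6 (-1.25 ± 0.52) and SOX17 (-7.04 ± 2.29, a fitted value with no read in TE) did not pass. Of 14 YAP and TEAD targets, 3 were higher and 0 lower, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.0405; adjusted p = 0.242 with an estimated correlation), led by DLC1 at 7.87 ± 0.75. Also called were the LIF and STAT3 list (0 of 10 members higher and 1 lower, also adjusted over the list alone; camera adjusted p = 0.0405; adjusted p = 0.242 with an estimated correlation), ribosomal proteins (0 of 12 members; adjusted p = 0.0264; adjusted p = 0.572 with an estimated correlation) and the cell cycle (0 of 25 higher and 1 lower, or 0 and 3 adjusted over the list alone; adjusted p = 0.0128; adjusted p = 0.524 with an estimated correlation), all lower in TE. The integrated stress response list was higher (1 of 15 higher and 0 lower, or 4 and 0 adjusted over the list alone; camera adjusted p = 0.0405; adjusted p = 0.242 with an estimated correlation). The genes given as higher or lower in these 2 paragraphs had adjusted p values from 0.000378 for KRT18 to 0.00708 for PDGFRA.

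The epithelial call was kept without each of the 4 embryo libraries, with a highest adjusted p of 0.163 over its alternatives. Without ICM 1, the calls were lost for trophoblast differentiation (adjusted p = 0.0763), the regulators and the hypoblast list (adjusted p = 0.136 for both), the naive list (adjusted p = 0.394), the YAP and TEAD list (adjusted p = 0.347), the ribosomal list (adjusted p = 0.506), the stress response list (adjusted p = 0.225), and the LIF and STAT3 and cell cycle lists (adjusted p = 0.136 for both). The naive call was also lost without TE 2 (adjusted p = 0.0712) or TE 3 (adjusted p = 0.0605), the hypoblast call without ICM 2 (adjusted p = 0.0973) or TE 3 (adjusted p = 0.17), and the YAP and TEAD call without TE 3 (adjusted p = 0.054). The LIF and STAT3 call was also lost without ICM 2 (adjusted p = 0.136) or TE 3 (adjusted p = 0.0822), the stress response call without TE 2 (adjusted p = 0.138) or TE 3 (adjusted p = 0.054). So were the ribosomal call without TE 3 (adjusted p = 0.233) and the cell cycle call without TE 2 (adjusted p = 0.127). With library size alone, the naive (adjusted p = 0.0588), hypoblast (adjusted p = 0.108), LIF and STAT3 and stress response (adjusted p = 0.0663 for both) calls were lost too. Without ICM 1, 1378 genes were higher and 836 lower in TE, without ICM 2, 700 and 858, and without TE 3, 208 and 102; without TE 2, 111 were lower. By camera, 10 of 31 lists were called, against 9 by fry, 1 without ICM 1 and 4 without TE 3, and SOX17 passed without ICM 2 (-8.04) and with DESeq2 (-6.35). Fitted with the ICM and TE libraries alone, 28 genes were higher and 22 lower. CDX2 (9.28), PKP2 (8.85), OCLN (6.19), DLC1 (7.89), NR5A2 (-11.59, a fitted value with no read in TE) and PDGFRA (-6.38) then did not pass. With library size alone, the share of called genes that were higher in TE went from 57.4% to 47.2% and the median of all genes from 0 to -0.23.

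The change of the cultured cells in trophoblast stem cell medium was set against the difference between TE and ICM, 2 contrasts that share no library. Across 8006 genes, Pearson's r of the log2 fold changes was 0.017 and Spearman's rho 0.024, and genes are not independent replicates. In the joint fit, 697 genes changed in culture and 545 differed in the embryo. Of the 74 called in both, 40 went the same way, where 47.4 and 22.8 would be reached if the contrasts were independent. As given above, LGALS3 was higher in both pLCDM-TSC and TE, and CDX2 and KRT18 fell in culture and were higher in TE. The interaction, (pLCDM-TSC minus pLCDM) minus (TE minus ICM), was positive in 329 genes and negative in 457. It was negative for CDX2 (-14.12 ± 1.50), KRT18 (-9.47 ± 0.56), KRT8 (-8.52 ± 0.84) and GATA2 (-10.25 ± 1.61), and positive for FN1 (8.80 ± 0.87) and STAT3 (5.89 ± 0.68), with adjusted p values from 9.12e-05 for KRT18 to 0.00691 for GATA2 by edgeR. KRT8 and GATA2 were higher in TE than in ICM, and FN1 and STAT3 lower. The sign of the interaction therefore does not give the direction of their change in culture. By camera, 11 of 31 lists were called, and 11 by fry. Of 17 genes of epithelial junctions and keratins, 0 had a positive and 9 a negative interaction, also adjusted over the list alone (camera adjusted p = 0.000578; adjusted p = 0.241 with an estimated correlation). Of 17 fibroblast and mesenchyme genes, 3 had a positive and 0 a negative interaction, also adjusted over the list alone (camera adjusted p = 0.000578; adjusted p = 0.243 with an estimated correlation). Both list calls were kept without each of the 8 libraries concerned. Among the other lists called, the LIF and STAT3 list was positive and also kept its call without each library. The hypoblast list and that of integrins and laminins were positive too. Trophoblast differentiation, glycolysis and cholesterol synthesis were negative. The trophoblast differentiation call was lost without each library other than pLCDM-TSC 2. Without ICM 1 or 2, 2215 and 2168 genes had an interaction, without pLCDM 1 or 2, 250 and 239, without pLCDM-TSC 1 or 2, 238 and 405, and without TE 2, 470. The list calls numbered 6 without ICM 2 and 7 without pLCDM 1 or TE 3, r was 0.051 without ICM 1 and -0.02 without ICM 2, and GATA2 did not pass without pLCDM-TSC 1 (-9.53).

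**Figure D3:**
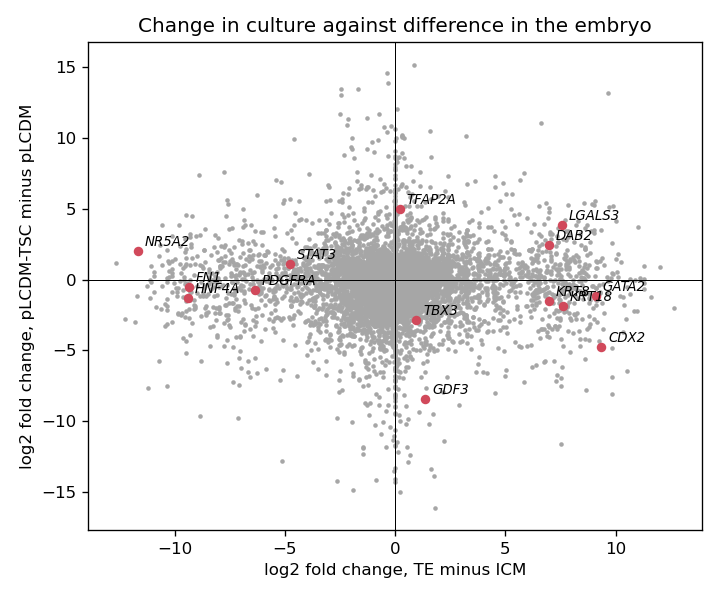
Log2 fold change of pLCDM-TSC minus pLCDM on the vertical axis against TE minus ICM on the horizontal axis; each point is a gene of the joint fit and 14 named genes are marked. CDX2, KRT18 and GATA2 lie far to the right and below 0 on the vertical axis, and r across genes is 0.017.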

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

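The results below were picked out by rules fixed before the data were examined, either because 2 contrasts differed by a test or because the deposited FPKM hold reads where the counts hold none.

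The change from pLCDM to pLCDM-TSC differed from that from ICM to TE in 786 genes by edgeR. Among the genes named in the text, the difference of the log2 fold changes was negative for CDX2 (-14.12), GATA2 (-10.25), GDF3 (-9.81), KRT18 (-9.47), KRT8 (-8.52), FURIN (-7.03), DAB2 (-4.56), TBX3 (-3.79) and LGALS3 (-3.71). It was positive for NR5A2 (13.71), FN1 (8.80), HNF4A (8.08), STAT3 (5.89), PDGFRA (5.65) and TFAP2A (4.82). A positive value is not by itself a rise in pLCDM-TSC, nor a negative one a fall. As given above, NR5A2, FN1, HNF4A, STAT3 and PDGFRA were lower in TE than in ICM, which enters their values. DAB2 and LGALS3 were higher in both pLCDM-TSC and TE, by less in the cultured cells. The value of NR5A2, which had no read in TE, is a fitted one and not exact. Some of these did not pass when a library was left out: GATA2 without pLCDM-TSC 1 (-9.53), TBX3 without pLCDM-TSC 1 (-3.65), FURIN without pLCDM 1 (-6.59), PDGFRA without pLCDM 1, pLCDM 2 or pLCDM-TSC 1 (5.60, 5.57 and 5.24), DAB2 without pLCDM 1, pLCDM 2, pLCDM-TSC 1 or TE 3 (-4.03, -5.01, -3.92 and -4.18), and TFAP2A without pLCDM 1, pLCDM 2, pLCDM-TSC 1, TE 2 or TE 3 (4.63, 4.77, 4.27, 4.86 and 4.57). With the libraries of these 4 groups fitted alone, PDGFRA (5.65) and TFAP2A (4.84) did not pass, nor did TFAP2A with limma-voom (4.13).

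For 13 genes, every embryo library had 0 counts and an FPKM above 1. The lowest FPKM of the 4 embryo libraries was 4970 for FTL, 589 for TPI1, 90.7 for RNASEH2C, 55.4 for PSME1, 43.6 for SLC39A7, 42.8 for PPP1CA, 35.6 for TRMT112, 18.1 for NKIRAS2, 9.89 for PFN1, 2.96 for EGFL8, 2.86 for PPOX, 2.80 for HYI and 1.34 for TMEM101. The values in counts for these genes in the embryo groups are therefore not taken as absence of the transcript.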

How the results depend on the processing

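Leaving out 1 library leaves a group with 1 sample, which is then assumed to vary like the other groups. The cause of the changes was not tested.

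For pLCDM-TSC minus pLCDM (1087 genes higher, 1450 lower), the joint fit of all 5 groups called 256 and 441, and leaving out 1 library 521 to 1291 and 802 to 1647. On FPKM with limma, 3848 genes were higher and 529 lower, 3882 and 538 with a pseudocount of 0.1, and 4431 and 678 without a filter. The length implied by counts and FPKM follows the gene span with r of 0.94 in pLCDM and 0.55 in pLCDM-TSC, across genes that are not independent replicates, so FPKM are not comparable between these groups. The same holds for pLCDM against ICM (r of 0.38 and 0.35) and TE (0.41 and 0.37). Genes that took the other sign on FPKM (FPKM + 1, FPKM + 0.1, no filter) were COL4A2 (1.04, 1.53, 1.04), DNMT3A (1.66, 2.26, 1.66), DNMT3B (0.15, 0.24, 0.15), FBLN2 (0.28, 0.30, 0.28) and SOX17 (-1.21 and -1.38 with the filter). GATA4 (-0.52) and SPINT1 (-0.47) did not pass on FPKM, nor DAB2 with limma-voom (2.11), nor F11R with library size alone (0.84). On FPKM, CDH1 (3.23), EPCAM (1.83) and GATA6 (2.13) passed, and VIM (1.87) with a pseudocount of 0.1. Without a filter, ETV4 (-0.44), TEAD4 (-0.02), ITGB6 (1.68), CYCS (0.89), SESN2 (-0.62) and STC2 (-1.08) did not pass. List calls went from 0 to 1 with library size alone and were 0 to 4 over left-out libraries. With library size alone, 31.1% of the called genes were higher, against 42.8%, and the median moved from -0.03 to -0.26.

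For pLCDM minus pPSC(KOFL) (2745 higher, 2189 lower), the joint fit called 867 and 627, and library size alone 1369 lower. With an estimated correlation, 0 lists were called. The 3 alternatives on FPKM were planned but are given as not run. The pPSC(KOFL) columns of counts and of FPKM can both be matched to the group alone, and only those of counts were kept. The FPKM alternatives had been run once before this was seen. They had called far fewer genes higher and more lower than the counts did, with SOX17, EPCAM and PKP2 on the other side. The values of that run are not given here. No paired analysis was possible here, because the pPSC(KOFL) columns map to the group only, nor for TE, which shares fewer than 2 numbers with pLCDM.

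For pLCDM minus ICM (357 higher, 199 lower), the counts were 759 and 362 with the strict filter, 1606 and 950 with DESeq2, 1466 and 424 with limma-voom, and 1828 and 1055 in the joint fit. Leaving out 1 library gave 288 to 3247 higher and 121 to 1914 lower. On FPKM, 2903 genes were lower, 3148 with a pseudocount of 0.1, and 755 were higher and 2133 lower without a filter. Without the genes at 0 in a group, an alternative added after the data were seen, 104 were higher and 96 lower. CDH1 took the other sign on FPKM (-2.71, -3.30 and -2.71), where FN1 (1.17) and PGK1 (0.09) did not pass and EPCAM (-3.36), GATA3 (1.27, but not without a filter), GATA6 (-4.48), PDGFRA (-2.86) and SOX17 (3.30) did. Without a filter, DLC1 (0.28), LEF1 (1.59) and TFAP2A (-2.87) did not pass. CDH1 (2.90) and GDF3 (3.83) did not pass with upper quartile scaling, nor did CDH1 (3.03), GDF3 (3.98) and PKP2 (11.11) without the genes at 0. List calls were 0 with an estimated correlation and 1 to 6 over left-out libraries.

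With the replicate number as a block, 735 genes were higher and 366 lower for pLCDM minus ICM, where GATA3 (4.57) and GATA6 (-2.85) passed, and 757 and 1204 for pLCDM-TSC minus pLCDM, where DAB2 (2.12), DNMT3A (-1.10) and F11R (1.08) did not pass. The deviations of equal numbers correlated at 0.01 and -0.28 across genes, which are not independent replicates, and the numbers are not stated to be pairs.

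For pLCDM minus TE (2319 higher, 1543 lower), FPKM gave 478 and 3920, 473 and 3969 with a pseudocount of 0.1, and 1040 and 3768 without a filter. Without the genes at 0, added after the data were seen, 1401 were higher. Leaving out 1 library gave 1166 to 2751 and 882 to 1809. CDH1 (-2.87, -3.47, -2.87) and EPCAM (-3.13, -3.16, -3.13) took the other sign on FPKM, where GATA6 (-3.27) passed and GDF3 (0.66) did not, nor, without a filter, did PDGFRA (0.27) and SPP1 (1.83). With an estimated correlation, 0 lists were called.

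For TE minus ICM (313 higher, 232 lower), DESeq2 gave 828 and 850, limma-voom 502 higher, the 2 groups alone 28 and 22, and left-out libraries 208 to 1378 and 102 to 858. List calls were 0 with an estimated correlation, 6 with library size alone and 1 to 9 over left-out libraries. The interaction (786 genes) had 1870 genes with DESeq2, 363 with its own groups alone and 238 to 2215 over left-out libraries, with 0 list calls with an estimated correlation and 6 to 9 over left-out libraries. The correlation of the contrasts (0.017) went from -0.02 to 0.051 over left-out libraries.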

Other observations

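Beside the groups described above, single genes of stress and mitochondrial lists changed from pLCDM to pLCDM-TSC. CYCS, cytochrome c, rose by 1.93 ± 0.27, and 5 of 12 nuclear genes of oxidative phosphorylation rose and 0 fell, or 6 and 0 adjusted over the list alone (camera adjusted p = 0.194). PMAIP1, a pro-apoptotic p53 target, rose by 2.34 ± 0.34, and SESN2, another p53 target, fell by 2.69 ± 0.40 (4 of 12 p53 genes rose and 1 fell, also adjusted over the list alone; camera adjusted p = 0.522). STC2, a secreted stress response protein, fell by 2.54 ± 0.44, with 0 of 16 stress response genes higher and 6 lower, also adjusted over the list alone (camera adjusted p = 0.194). IFI44L, an interferon-induced gene, was at least 101-fold higher, with 3 of 12 interferon genes higher and 0 lower, also adjusted over the list alone (camera adjusted p = 0.182). These genes had adjusted p values from 0.00491 to 0.00887 by edgeR. Fitted together with the other 3 groups, CYCS (2.00) and IFI44L (10.90, a fitted value with no read in pLCDM) did not pass.

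Posterior and intestinal genes were looked at because CDX2 also acts in the hindgut, and the genes named here were chosen after their values were seen. HOXA7 stood at 36.4 CPM in pLCDM, 3.86 in pLCDM-TSC and 13.4 in pPSC(KOFL), HOXB8 at 3.68, 0.186 and 0, and ANPEP, a brush border peptidase, at 34.6, 11.1 and 3.16. SI, an intestinal disaccharidase, stood at 52.8, 85 and 78 CPM. Of 18 genes tested, 11 were higher in pLCDM than in pPSC(KOFL), or 61.1%, against 2745 of all 7557 genes, or 36.3% (exact p = 0.0461, across genes that are not independent). By the same count, 3 of 19 tested were higher in pLCDM than in pLCDM-TSC, or 15.8%, against 18.6% of all genes (exact p = 1). The same 3 were higher than in both, 15.8% with an interval of 3.38 to 39.6%, which leaves open whether CDX2 is read as part of such a programme.

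Some tests here were chosen only after the result was seen: the shares of posterior genes beside those of all genes, the overlap of genes near 0 in the embryo, the one on embryo FPKM, the corrected correlation, and the comparison of collagen with FN1. The other tests were written before, though the one on the pLCDM libraries names COL3A1 as already differing between them.

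Some genes had reads in some groups and almost none in another: 66 of 3428 genes read in every cultured library had at most 2 counts in every embryo library, 1 of 3355 the other way round, and 31 genes read in all other groups had at most 2 counts in each library of 1 group. Reads lost where gene models overlap a neighbour could produce these, and an odds ratio of 1.65 (0.757 to 3.58, exact p = 0.189, 15 of 31) leaves that open for the last set, but it was 1 (0.578 to 1.7, exact p = 1, 24 of 66) for the first and 0.868 (0.507 to 1.45, exact p = 0.623, 24 of 71) for genes over 32-fold lower in pLCDM than in both other cultured groups, which speaks against it there. Different gene lengths could as well, with a ratio of 1.08 (0.775 to 1.34) leaving that open, and the length implied by counts and FPKM followed the gene span with r of 0.94 in pLCDM and 0.35 to 0.55 in pLCDM-TSC, ICM and TE, across genes that are not independent. Counting pLCDM reads over whole genes would go with that r. Positive differences between long and short genes were then predicted for pLCDM against both other cultured groups. The difference of -0.14 (-0.28 to 0.05) against pPSC(KOFL) argues against such counting in pLCDM alone. It cannot tell whether both groups were counted so, since the pPSC(KOFL) FPKM were not used. The difference of -0.87 (-0.98 to -0.74) against pLCDM-TSC cannot decide. A value near 0 was predicted for pLCDM-TSC minus pPSC(KOFL), but 0.89 (0.75 to 1.04) places a length trend in pLCDM-TSC. Long and short genes were not compared between pLCDM and ICM or TE. Embryo counts lost where the FPKM still hold reads are argued against for most of the genes tested. Of 321 genes at 0 counts in ICM and at 10 CPM or more in every pLCDM library, 6 had an FPKM above 1 in both ICM libraries, or 1.87%. A loss before both counts and FPKM were made would not show in this test.

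Across genes, the change in trophoblast stem cell medium had almost no correlation with the difference between TE and ICM (r of 0.017). The trend with gene length in the fold changes of pLCDM-TSC enters this contrast, and its effect on r was not tested. Spread between libraries might hide a shared change: between separate pairs of libraries, r across genes, which are not independent replicates, was 0.743 and 0.841 for the culture but 0.277 and 0.355 for the embryo contrast, short of the 0.5 set beforehand. The correlation corrected for this spread, chosen after the result was seen, was 0.038 but ran from -0.089 to 0.167 over single pairs of libraries, so this stays open. Genes without a read as the cause are argued against, since the correlation without them was 0.018 (-0.007 to 0.043, 6126 genes). That the medium selects or induces a state other than the trophectoderm of the blastocyst stays open too; of 9 amnion genes 1 rose and 1 fell, also adjusted over the list alone (median -0.40, mean 0.80, camera adjusted p = 0.91).

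Hypoblast genes were higher in pLCDM than in TE. Fibroblasts or feeder cells in the cultures could carry some of them, but these genes did not rise with COL3A1 between the pLCDM libraries. The median log2 ratio of pLCDM library 2 to 1 over 16 such genes was -0.46 (quartiles over genes -0.91 to -0.04). It was 4.41 for COL3A1, a collagen already seen to differ between these libraries. COL3A1 stood at 68 CPM, or 1.38% of FN1, and COL1A2 at 0.834 CPM beside 4930 CPM of FN1, a comparison made after the data were seen. COL3A1 lay above the level set for arguing against fibroblasts, so this comparison leaves them open. Counts lost in TE could do so too, but 0 of 11 members under 1 CPM in TE, or 0%, had an FPKM above 1 in both libraries. Reads lost before both counts and FPKM were made would leave no FPKM either, so this test cannot exclude them. Hypoblast-like cells in the cultures and hypoblast genes read in the pluripotent cells themselves might both give these levels, and bulk libraries do not separate the 2.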
